A study of Mus musculus with 29 samples.

How the data were processed

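Hearts of male C57BL/6N mice were profiled by RNA sequencing 1 h or 1 day after a single subcutaneous injection of isoprenaline or phenylephrine, with a separate control group for each drug. Per the labels' protocols, RNA was purified on poly-T beads, fragmented and copied with random hexamers, and fragments were selected by size before PCR. The protocols also mention hearts taken after 3 days, which are not analysed here. The submitters' processing notes name the genome build GRCm38.p6. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here, so genes that overlap or have an antisense partner are uncertain. Without strand information their reads cannot be told apart.

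Each deposited table lists 54532 genes with a count, an FPKM value and a TPM value. Per the file headers, the first of these is the deposited count of each gene, and it holds whole numbers with no normalization. The deposited FPKM values divide that count by gene length and by an effective library size. The factor the authors applied for it had a Pearson correlation of 0.9986 across the libraries with the factor computed here by the trimmed mean of M values (TMM). The deposited TPM values are the same numbers rescaled to a fixed sum. The counts alone were used for tests. Of the gene identifiers, 99.93% matched the mouse reference annotation at hand, and symbols and coordinates are those in the deposited tables. Where rows shared a symbol, the row with the most counts kept it.

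Genes with low counts were removed with filterByExpr, which left 15993 genes and at least 99.883% of the counts of each library. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood model with 1 mean per group over all 29 libraries, so that the 6 groups shared the estimate of spread. That left 23 residual degrees of freedom, with a median biological coefficient of variation of 0.1155. Each comparison was a 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Fold changes are log2, with the standard error taken from the F statistic. Levels are counts per 1000000 counts after TMM. The 9 comparisons were each drug and time against that drug's controls, the isoprenaline effect minus the phenylephrine effect at each time, 1 day against 1 h for each drug, and the control groups against each other.

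Before the data were examined, 33 gene lists were fixed for pathways and cell types of the heart. Some genes were members of several lists. Fn1 and Thbs1 stood in the monocyte and matrix lists, and Nppa in the hypertrophy and atrial lists. Nr4a1, Nr4a2, Nr4a3 and Fosl2 stood in the immediate early and cAMP lists. The lists are thus not independent of each other. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes and adjusted over the lists. For each list the members called are given over all tested genes and adjusted over the list alone. The genes that could be named were also fixed by rule. For each drug group against its controls these were the protein-coding genes with the largest changes each way among those called, at a mean of 1 CPM or more, with every treated library beyond every control library. For the other comparisons they were the largest changes each way without the condition on single libraries. The rule added the members of each list with the smallest p and the 6 adrenergic receptor genes. Which of these genes became examples in the text was decided after their values, and their values under the alternatives, had been seen. A gene with 0 counts in a group was compared with a floor of 3 counts over that group, and ratios from few counts have 95% counting intervals. Such intervals and floors cover counting error only, since PCR copies are not independent molecules.

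The libraries held between 16067496 and 19674879 counts, and 1 count was worth 0.0491 to 0.0676 CPM. Mitochondrial genes took 21.1% to 30.9% of the counts. Replicates of a group were compared by a chi-square test of their counts, and the statistic per gene lay between 6.07 and 49.99 over 56 pairs, so no library looked like a second copy of another. With library totals as the only scaling, the median of all genes shifted by more than 0.1 on the log2 scale in 6 comparisons. They were -0.119 for isoprenaline at 1 h, -0.159 and 0.167 for phenylephrine at 1 h and 1 day, -0.158 for the difference at 1 day, and 0.152 and 0.358 for 1 day against 1 h after isoprenaline and phenylephrine. Changes in the text are relative to the TMM scaling, and the split into higher and lower calls under library totals stands beside each count.

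The procedure was tested on simulated counts with 200 changed genes, drawn for each comparison from the observed means, library sizes and spread. For genes changed by a log2 fold change of 1, the share recovered was 81% for isoprenaline at 1 h, 79.8% for isoprenaline at 1 day, 64.3% for phenylephrine at 1 h and 74.5% for phenylephrine at 1 day. It was 63% and 59.2% for the differences between the drugs at 1 h and 1 day. Each simulated gene had the same spread in every group. The shares recovered thus do not show how the tests behave where 1 group varies more than the others. The camera step called 0 of the random lists of unchanged genes in any comparison. Each gene was drawn on its own, so these lists had no correlation between genes. The simulation thus cannot show how many false calls such correlation brings in the real lists.

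The alternatives were DESeq2 size factors, library totals, no filter, a filter at a mean of 1 CPM, robust spread, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. For the lists they were an estimated correlation, fry, DESeq2 size factors and the block. A fit without the 4 libraries with the highest interferon genes, and a fit with the level of atrial markers as a covariate, were added after the data had been seen.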

Results

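Polyadenylated RNA was sequenced from the hearts of adult male C57BL/6N mice after a single subcutaneous dose of an adrenergic agonist. Isoprenaline (ISO, 5 mg/kg) is a catecholamine with an N-isopropyl group that activates beta-adrenergic receptors. Phenylephrine (PE, 10 mg/kg) lacks the second ring hydroxyl of the catechols, carries an N-methyl group and activates alpha-1 receptors. Hearts were taken 1 h or 1 day after the injection. Each drug had its own control group, for which the labels give neither a sampling time nor an injected vehicle. Every group held 5 samples except the PE controls, which held 4, so 29 libraries entered the comparisons. Each library held between 16067496 and 19674879 counted reads over 54532 annotated genes. The filter on low counts left 15993 genes for testing. Levels are counts per 1000000 counts (CPM) as mean ± SD over those 5 or 4 samples, at which 1 read was worth 0.0491 to 0.0676 CPM. The labels do not say outright that replicates are separate mice. The p-values thus measure the spread between these samples, which may be technical in part.

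The first comparison set the hearts taken 1 h after isoprenaline against the ISO controls. No injected vehicle is given for these controls, so a response to the injection itself cannot be told apart from that to the drug. Immediate early genes, transcription factors and signal regulators that respond within minutes to a stimulus, rose almost as a block. Of this list, 27 of 28 members rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 3.56 (camera adjusted p = 8.43e-122). Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051 in GRCm38.p6), a protein-coding AP-1 subunit, went from 0.943 ± 0.400 to 247 ± 38.8 CPM (log2 fold change 8.01, SE 0.30, adjusted p = 8.61e-18). The orphan nuclear receptors Nr4a3 and Nr4a2 went from 1.84 ± 0.350 to 289 ± 78.2 CPM and from 1.79 ± 0.403 to 174 ± 41.3 CPM. Targets of cAMP and CREB, the route by which beta receptors signal, went the same way: 14 of 18 members rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 7.35e-55). Among them Crem, which encodes inducible repressors of CREB sites, reached 58.1 ± 6.995 CPM against 8.02 ± 0.653 (log2 fold change 2.86, SE 0.11, adjusted p = 7.58e-18). Feedback regulators of MAP kinase also changed (camera adjusted p = 1.36e-12): 7 of 13 members rose and 2 fell (8 and 3 adjusted over the list alone). Dusp5 (log2 fold change 3.73), a nuclear ERK phosphatase, and Spry4 (3.13) were among those that rose. Camera was run with a preset correlation between genes, and where a list's call was lost with an estimated correlation that p is given too.

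Stress and vascular genes rose at 1 h after isoprenaline as well. For heat shock proteins, 14 of 14 members rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 5.59e-13). Hsp90aa1 (log2 fold change 1.66) and Dnaja1 (1.78) were among them. Hspa1a reached 79.4 ± 65.9 CPM from 1.82 ± 0.477, a value uncertain because Hspa1b is a near-identical copy. Its log2 fold change of 5.44 was 4.81 without ISO 1 h replicate 1. Of the hypoxia and vascular growth factor list, 6 of 13 members rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00442). Plaur (log2 fold change 3.74), the urokinase receptor, and Vegfa (0.64) rose while Edn1 (log2 fold change -1.22), the endothelin-1 precursor, fell. Of cytokines and chemokines, 11 of 30 members rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0567). Cxcl1 (log2 fold change 3.22) and Osm (3.65; 4.50 without ISO control replicate 3 and 4.41 without the 4 libraries with the highest interferon genes described next) rose and Csf1 (log2 fold change -1.12) fell. The number lower was 3 without the 4 libraries, ISO control replicate 1 or 3 or ISO 1 h replicate 2, or with the replicate number as a block. It was 2 with only the compared groups in the fit. NF-kappaB targets and adhesion molecules had 9 of 17 members higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 3.73e-06, and adjusted p = 0.13 with an estimated correlation). Irf1 (-1.88) was the member that fell, with a value of -0.88 without those 4 libraries and -1.26 without ISO control replicate 3. With library totals alone or the replicate number as a block 2 were lower, and 3 without ISO control replicate 2 or ISO 1 h replicate 1. Nfkbiz (log2 fold change 2.29) and Tnfaip3 (1.60) led the rise. In the endothelial list the tight-junction gene Cldn5 (log2 fold change 3.25) rose and the VEGF receptor Kdr (log2 fold change -0.86) fell. The apelin receptor Aplnr fell from 54.2 ± 28.98 to 3.46 ± 0.932 CPM (log2 fold change -3.97, SE 0.42, adjusted p = 1.83e-08). The potassium channel gene Kcnj2 fell (log2 fold change -1.52, SE 0.15, adjusted p = 5.69e-09).

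Interferon response genes were lower at 1 h after isoprenaline than in the ISO controls: 0 of 30 members rose and 24 fell (0 and 29 adjusted over the list alone; camera adjusted p = 2.5e-06, and adjusted p = 0.739 with an estimated correlation). The 5 ISO controls were unlike each other in these genes. Their mean log2 CPM over the list ran from 3.54 to 7.11, against 3.65 to 4.16 in the PE controls. ISO control replicates 1, 3 and 4 and ISO 1 h replicate 1 stood highest. Without those 4 libraries, 10 of the 30 members were lower at 1 h and 0 at 1 day (8 at an unadjusted p under 0.05), and with only the compared groups in the fit 8 were lower at 1 h. Resident macrophage markers moved with them: 0 of 14 members rose and 9 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.00573, and adjusted p = 0.739 with an estimated correlation). Cx3cr1 (log2 fold change -2.23) led them, and without the 4 libraries 1 member was lower and 1 higher (camera adjusted p = 0.349). Without ISO control replicate 3 alone, or with only the compared groups, 4 were lower. In all, 4736 genes differed at 1 h after isoprenaline, 2294 higher and 2442 lower. Of these 449 and 591 passed a 2-fold change (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, as throughout). Scaling by library totals alone turned the split to 1171 higher and 3725 lower. Without the 4 interferon-high libraries 2576 genes differed.

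**Figure D1:**
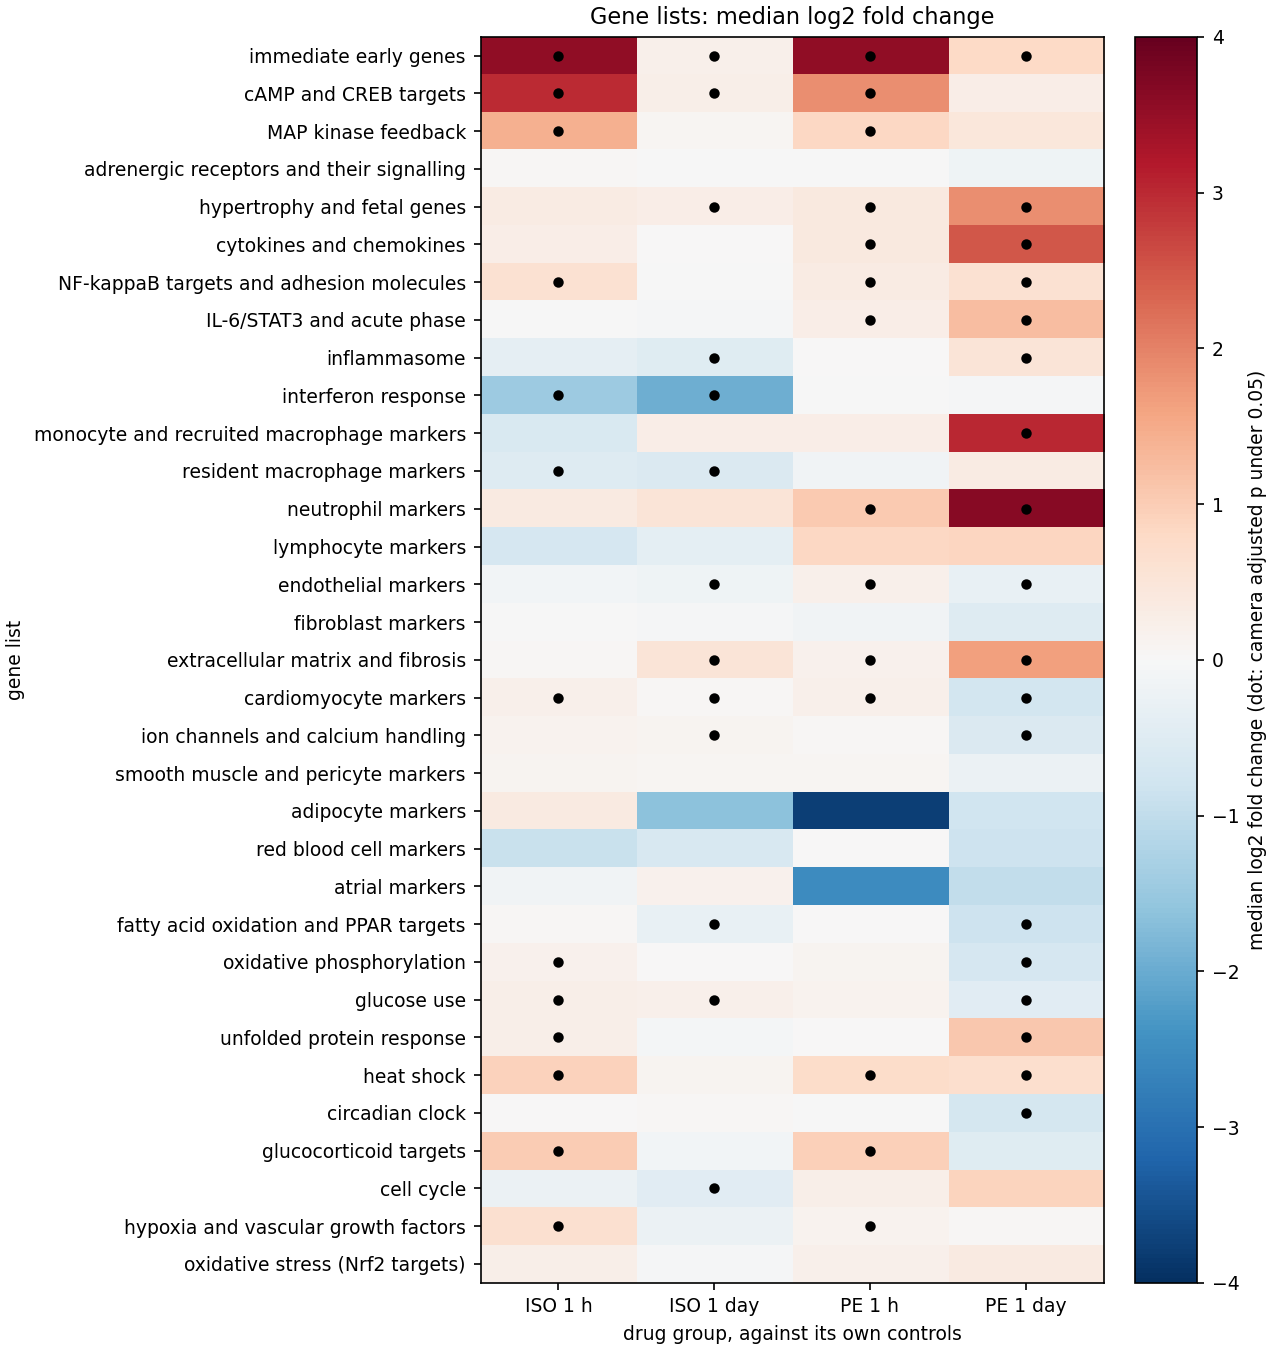
Median log2 fold change of the 33 gene lists in each drug group against its own controls, with 1 row per list and 1 column per comparison. Each cell is the median over the tested members, and a dot marks lists with a camera adjusted p under 0.05. Immediate early genes reach 3.56 and 3.55 at 1 h, and monocyte markers reach 3.03 at 1 day after phenylephrine.

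By 1 day after isoprenaline fewer genes differed from the controls. Nmrk2, a nicotinamide riboside kinase of the NAD salvage route, rose from 6.78 ± 2.02 to 75.5 ± 37.3 CPM (log2 fold change 3.48, SE 0.30, adjusted p = 2.8e-08). The muscle LIM-domain gene Fhl1 rose from 107 ± 8.57 to 423 ± 39.1 CPM (log2 fold change 1.99, SE 0.11, adjusted p = 3.71e-12). Of the extracellular matrix list, 7 of 23 members rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 3.57e-08, and adjusted p = 0.291 with an estimated correlation). The tenascin gene Tnc (log2 fold change 2.66), Timp1 (2.07) and Col8a1 (0.98) were among them. Osteopontin, Spp1, rose from 1.25 ± 1.28 to 15.8 ± 16.4 CPM (log2 fold change 3.63; 2.75 without ISO 1 day replicate 1, 4.50 without ISO control replicate 1 and 4.68 without the 4 interferon-high libraries). Angiotensinogen, Agt, rose from 2.99 ± 1.22 to 13.9 ± 7.03 CPM and had stood at 15.5 ± 2.13 CPM at 1 h. Fatty acid oxidation genes and PPAR targets fell: 0 of 25 members rose and 10 fell (0 and 15 adjusted over the list alone; camera adjusted p = 5.6e-13, and adjusted p = 0.259 with an estimated correlation). Ucp3 (log2 fold change -1.86) and the thioesterase gene Acot1 (-2.09; -1.38 without ISO control replicate 3 and -1.33 without the 4 interferon-high libraries) fell. Pdk4, a brake on pyruvate oxidation, went from 672 ± 484 to 147 ± 38.6 CPM, a change of -2.19 that was -1.18 and not called without the 4 interferon-high libraries. The alpha-1A receptor gene Adra1a fell (log2 fold change -0.74, SE 0.13, adjusted p = 0.000497). Of the immediate early genes, 5 of 28 were still above the controls (6 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.735 with an estimated correlation). Without the 4 interferon-high libraries 0 of the 28 were called (11 higher at an unadjusted p under 0.05; camera adjusted p = 0.000836). The number was 3 without ISO control replicate 3 or with only the compared groups, and 2 without ISO 1 day replicate 3. In turn 27 were lower at 1 day than at 1 h in the direct test (camera adjusted p = 2.24e-113).

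Interferon response genes made up part of this comparison too: 0 of 30 members rose and 29 fell (0 and 30 adjusted over the list alone; camera adjusted p = 6.91e-28, and adjusted p = 0.259 with an estimated correlation). Resident macrophage markers were again lower, 8 of 14 (11 adjusted over the list alone; camera adjusted p = 2.76e-07, and adjusted p = 0.291 with an estimated correlation), and 0 were without the 4 interferon-high libraries (1 at an unadjusted p under 0.05; camera adjusted p = 0.578). The number was 1 with only the compared groups or without ISO control replicate 3, 3 without ISO control replicate 1, and 4 or 5 with library totals alone, no filter or any ISO 1 day library left out. Of the endothelial markers 2 of 15 were lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.00468, and adjusted p = 0.582 with an estimated correlation). The number was 1 with no filter or only the compared groups. It was 0 without the 4 libraries, ISO control replicate 3 or ISO 1 day replicate 1 (4 unadjusted each), and 0 without ISO 1 day replicate 3 or 4 (5 unadjusted each). In total 1343 genes differed at 1 day after isoprenaline, 678 higher and 665 lower. The split was 827 higher and 527 lower with library totals alone. The count moved with the libraries in the fit. It was 184 without the 4 interferon-high libraries, a fit that leaves 2 ISO controls. With all other libraries kept, 2 ISO controls gave 160 (replicates 2 and 5), 229 (replicates 1 and 2) and up to 1308 (replicates 1 and 3). The fall to 184 thus cannot be put down to the interferon-high libraries alone. The count was 864 without ISO control replicate 3 and 761 with only the 2 groups in the fit. Without the 4 libraries 2 fatty acid oxidation genes were lower, against 10, and 4 matrix genes higher, against 7 (camera adjusted p = 5.37e-09 and 5.05e-11). Without ISO control replicate 3 alone these numbers were 5 and 4. The matrix number was also 4 without ISO control replicate 2 or with only the compared groups, and 11 without ISO control replicate 1.

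Phenylephrine was examined in the same way at 1 h. Immediate early genes rose as a group: 27 of 28 members rose and 0 fell (27 and 0 adjusted over the list alone; camera adjusted p = 1.96e-224). Fos went from 2.60 ± 1.52 to 462 ± 86.3 CPM (log2 fold change 7.49, SE 0.40, adjusted p = 3.8e-14) and the stress factor Atf3 from 5.10 ± 2.65 to 678 ± 130.5 CPM. Of the cAMP and CREB targets, 12 of 18 members rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.17e-40). Of the MAP kinase feedback genes 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 5.1e-22). Hypertrophy and fetal genes, the set that marks cardiomyocyte growth, rose at this early time: 6 of 14 members rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 2.13e-08). Xirp1, an actin-binding protein of the intercalated disc, went from 176 ± 29.5 to 1295 ± 227 CPM (log2 fold change 2.88, SE 0.16, adjusted p = 8.55e-14). Rcan1 (log2 fold change 1.99), a calcineurin regulator, Ctgf (2.58) and Nppb (1.80), the B-type natriuretic peptide gene, also rose. With library totals alone 1 hypertrophy gene and 1 cAMP target were lower, and 1 hypertrophy gene was with DESeq2 or without PE control replicate 2. In each of these settings all 7 atrial markers were lower at an unadjusted p under 0.05. Among them was Nppa, which is in the hypertrophy list as well. For heat shock proteins, 10 of 14 members rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 3.86e-17). Of the hypoxia and vascular list, 5 of 13 members rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 2.03e-07). Edn1 (log2 fold change 2.36) and Hbegf (2.84) were among them, although the median of the list, 0.13, was -0.03 with library totals alone.

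Inflammatory signals were already higher at 1 h after phenylephrine. Of cytokines and chemokines, 12 of 30 members rose and 0 fell (13 and 2 adjusted over the list alone; camera adjusted p = 6.68e-06, and adjusted p = 0.206 with an estimated correlation). Under library totals alone, in DESeq2 or with the replicate number as a block, the number lower was 2. It was 1 with DESeq2 size factors, the filter at 1 CPM or only the compared groups. Without the 4 interferon-high libraries or PE control replicate 2 or 4 it was 1 as well. Cxcl1 rose (log2 fold change 3.63, SE 0.21, adjusted p = 2.52e-13). Il6 held 241 reads over the 5 treated libraries against 3 over the 4 controls. The log2 fold change was 6.02, or 6.96 without PE control replicate 3. The ratio was 76.2 after scaling with a 95% counting interval of 25.8 to 372. NF-kappaB targets had 9 of 17 members higher and 0 lower (9 and 2 adjusted over the list alone; camera adjusted p = 1.79e-07, and adjusted p = 0.0638 with an estimated correlation). With library totals alone 5 were higher and 2 lower, and 2 were lower without the 4 interferon-high libraries. The number lower was 1 with DESeq2, the replicate number as a block or only the compared groups, or without PE control replicate 2. Nfkbiz (log2 fold change 2.40) and the prostaglandin synthase gene Ptgs2 (3.44) rose. Neutrophil markers moved with them, 4 of 11 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.628 with an estimated correlation), Il1r2 (log2 fold change 1.96) and Trem1 (2.41) among them. The number was 2 without PE control replicate 2 or PE 1 h replicate 1, and 1 with only the compared groups. Il1r2 rests on few reads: it lay at 0.156 to 0.182 CPM in the PE controls and 0.526 to 0.978 CPM at 1 h. Endothelial markers had 4 of 15 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.57 with an estimated correlation), and 2 higher with library totals alone. The matrix-linked genes Serpine1 and Thbs1 rose by log2 fold changes of 4.48 and 4.71. The fibroblast genes Pdgfra (log2 fold change -0.63) and Tcf21 (-1.04) and the beta-1 receptor gene Adrb1 (log2 fold change -0.88, SE 0.12, adjusted p = 1.82e-06) fell. Atrial and adipocyte markers stood low in the PE 1 h hearts, with median log2 fold changes of -2.52 and -3.77. Of 7 and 9 members Bmp10 and Ucp1 alone passed the test, with 4 and 1 reads in those hearts. Both calls were lost when a single library was left out, PE control replicate 3 (-6.19 from -11.91) for Bmp10 and PE control replicate 1 (-0.37 from -10.26) or any PE 1 h library for Ucp1. Both calls were lost with the level of atrial markers as a covariate too, and the Ucp1 call was lost with robust spread. With only the compared groups in the fit 0 atrial markers were lower. Other fits called more: 3 atrial and 5 adipocyte markers were lower with library totals alone, 2 and 5 with DESeq2, and 3 of each without PE control replicate 2. The number of adipocyte markers lower was 5 without the 4 interferon-high libraries and 4 with only the compared groups. It was 2 without PE control replicate 3 or 4 or with the replicate number as a block. Without PE 1 h replicate 2, 2 atrial markers were lower. Their levels ran over a wide range among the PE controls themselves, where the mean log2 CPM of the atrial list lay between 0.26 and 8.8. In total 2061 genes differed, 1176 higher and 885 lower. Of these 341 and 225 passed a 2-fold change. With library totals as the only scaling 3827 genes differed, 605 higher and 3222 lower.

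**Figure D2:**
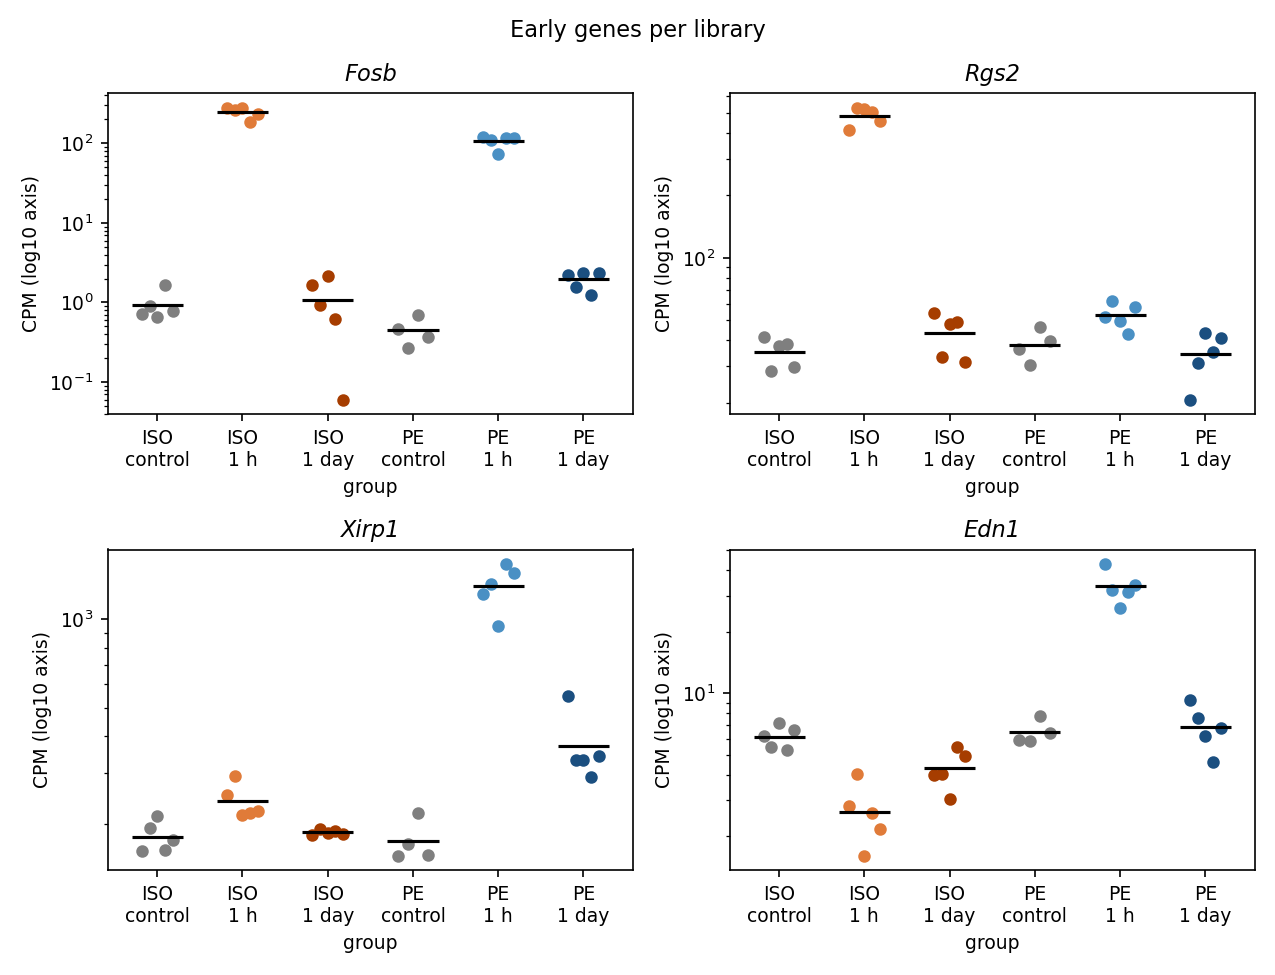
Level of Fosb, Rgs2, Xirp1 and Edn1 in each library, in CPM on a log10 axis, by group. Points are libraries and bars are group means. Fosb is high at 1 h after either drug, Rgs2 has a mean of 482 CPM at 1 h after isoprenaline against 52.9 after phenylephrine, and Xirp1 and Edn1 are higher after phenylephrine.

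At 1 day after phenylephrine the heart differed from its controls far more widely. Markers of monocytes and recruited macrophages all rose: 15 of 15 members rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 3.03 (camera adjusted p = 1.32e-08, and adjusted p = 0.148 with an estimated correlation). The arginase gene Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), went from 0.204 ± 0.234 to 67.4 ± 21.03 CPM (log2 fold change 8.37, SE 0.51, adjusted p = 5.42e-13; 9.43 without PE control replicate 4). The monocyte chemokine receptor gene Ccr2 went from 8.14 ± 2.97 to 114 ± 25.3 CPM. Of the neutrophil markers, 9 of 11 members rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 7.03e-06, and adjusted p = 0.148 with an estimated correlation). The interleukin-1 decoy receptor gene Il1r2 (log2 fold change 5.16) and Cxcr2 (4.58) were among them. Of cytokines and chemokines, 22 of 30 members rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 9.45e-08, and adjusted p = 0.146 with an estimated correlation). Ccl11 fell (-0.81), and 2 were lower without PE control replicate 3, without the 4 interferon-high libraries or with only the compared groups. Ccl2, the ligand of Ccr2, rose from 2.82 ± 0.909 to 76.3 ± 14.8 CPM and Spp1 from 2.57 ± 1.22 to 292 ± 104 CPM. Of the IL-6/STAT3 and acute phase list, 14 of 18 members rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 8.71e-07, and adjusted p = 0.163 with an estimated correlation). The inflammasome genes Il1b (log2 fold change 4.54) and Nlrp3 (2.82) rose. In their list 8 of 12 members rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0497, and adjusted p = 0.463 with an estimated correlation). Tarm1, an activating receptor of myeloid cells, had 0 reads in the PE controls and was at least 53.6-fold higher at 1 day, against a floor of 3 counts over the control group. Of 30 interferon response genes 1 passed the test, Oas1a (1.11; 1 adjusted over the list alone). In other fits 3 were higher with library totals alone, 6 higher and 4 lower without the 4 interferon-high libraries, and 7 higher and 3 lower with only the compared groups. The number higher was 5 with the replicate number as a block and 2 with the level of atrial markers as a covariate. The red blood cell markers had a median of -0.82 with 0 of 6 higher.

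**Figure D3:**
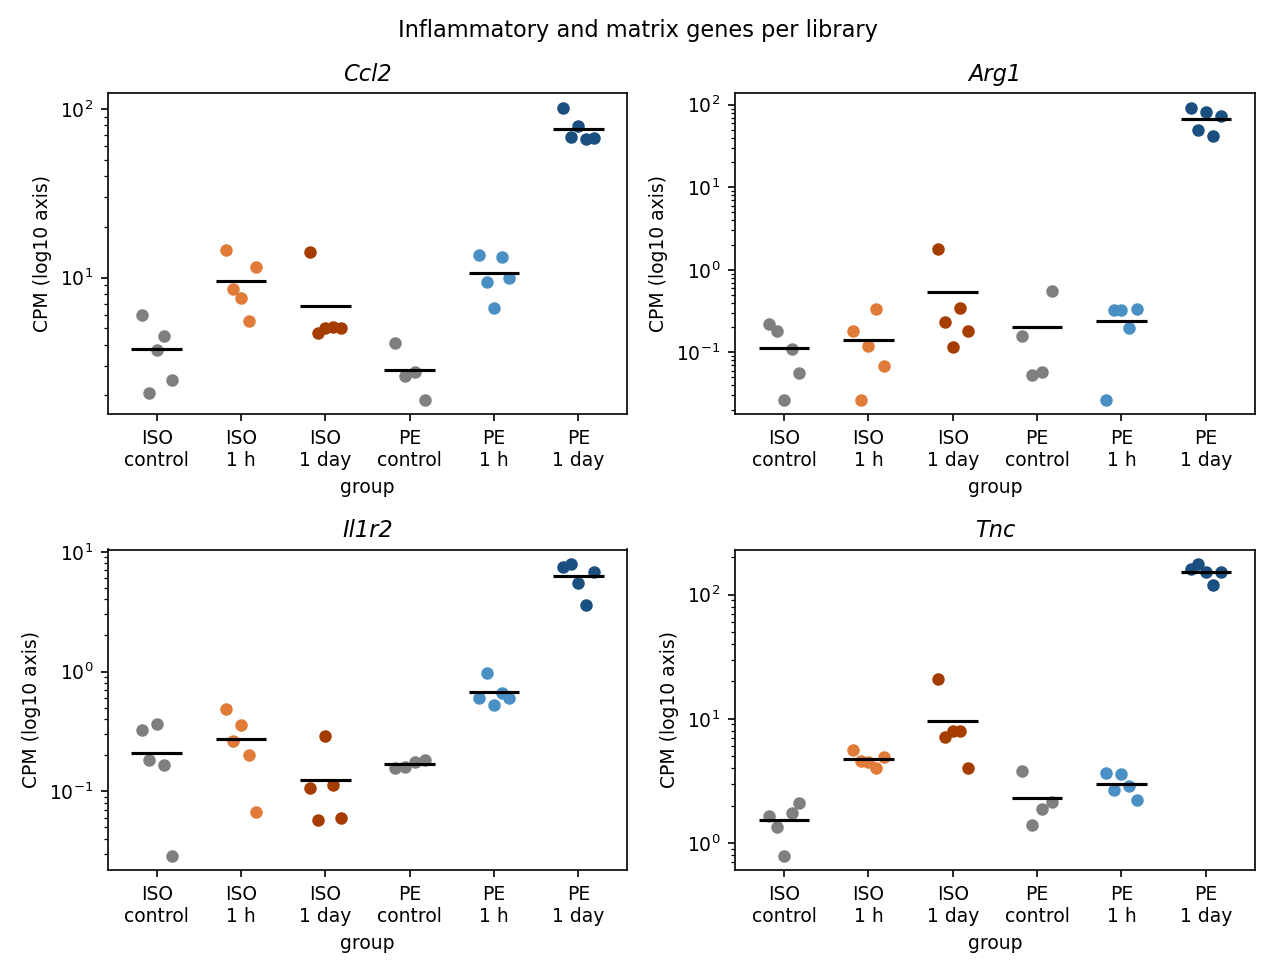
Level of Ccl2, Arg1, Il1r2 and Tnc in each library, in CPM on a log10 axis, by group. Points are libraries, bars are group means, and libraries with 0 reads are drawn at the bottom of the axis. All 5 PE 1 day libraries lie above every PE control for each of the 4 genes.

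Matrix and growth genes rose with them. Of the extracellular matrix and fibrosis list, 21 of 23 members rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 2.69e-13, and adjusted p = 0.0869 with an estimated correlation). The exception, the gelatinase gene Mmp2 (-0.65), was picked for naming after its values were seen. Tnc went from 2.29 ± 1.05 to 152 ± 20.4 CPM (log2 fold change 6.04, SE 0.34, adjusted p = 1.13e-13) and Timp1 from 3.25 ± 1.36 to 186 ± 32.2 CPM. The collagen crosslinker gene Lox (log2 fold change 2.79) rose. The fibroblast markers split, with 5 of 14 higher and 7 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.145). Pdgfra (log2 fold change 0.69) rose while Scara5 (log2 fold change -1.84) and Islr (-1.36) fell. Of hypertrophy and fetal genes, 10 of 14 members rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.28e-08). Xirp2 (log2 fold change 3.04), Fhl1 (3.30) and Nppb (2.74) were higher and Fhl2 (-1.02) was lower, with 2 lower without PE 1 day replicate 1. The stretch-responsive muscle gene Ankrd2 went from 0.301 ± 0.149 to 36.1 ± 7.72 CPM (log2 fold change 6.90, SE 0.34, adjusted p = 1.04e-14). Sprr1a, a small proline-rich stress protein, held 4166 reads against 4 in the controls. Genes of the unfolded protein response rose, 11 of 15 against 2 that fell (11 and 3 adjusted over the list alone; camera adjusted p = 6.71e-08, and adjusted p = 0.0869 with an estimated correlation). Manf (log2 fold change 1.85) and Xbp1 (1.11) were among those that rose. Of its members 1 was lower without PE control replicate 4.

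Genes of contraction, excitation and energy supply fell at 1 day after phenylephrine. For cardiomyocyte markers, 0 of 16 members rose and 13 fell (0 and 13 adjusted over the list alone; camera adjusted p = 1.32e-08, and adjusted p = 0.148 with an estimated correlation). Myh6, the main myosin heavy chain of the adult mouse heart, went from 15420 ± 542 to 5976 ± 889.9 CPM (log2 fold change -1.37, SE 0.09, adjusted p = 1.16e-12). For ion channels and calcium handling, 2 of 27 members rose and 20 fell (2 and 20 adjusted over the list alone; camera adjusted p = 1.94e-08, and adjusted p = 0.0869 with an estimated correlation). The potassium channel subunit gene Kcnip2 fell from 146 ± 25.3 to 22.4 ± 4.91 CPM. Atp2a2 (log2 fold change -1.36), the calcium pump gene of the sarcoplasmic reticulum, fell too. Of the oxidative phosphorylation list, 0 of 22 members rose and 22 fell (0 and 22 adjusted over the list alone; camera adjusted p = 5.69e-12, and adjusted p = 0.163 with an estimated correlation), with a median of -0.67. Of fatty acid oxidation and PPAR targets, 2 of 25 members rose and 21 fell (2 and 21 adjusted over the list alone; camera adjusted p = 1.32e-08, and adjusted p = 0.147 with an estimated correlation). Angptl4 (2.44) was among those that rose, of which 1 was called without PE control replicate 2 or 3 or PE 1 day replicate 1. Of the glucose use list 3 of 18 members rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.00058, and adjusted p = 0.279 with an estimated correlation). The insulin-responsive transporter gene Slc2a4 (log2 fold change -1.60) fell and Slc2a1 (log2 fold change 1.28) rose, and with library totals alone 5 members were higher. Endothelial markers had 8 of 15 lower and 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.0477, and adjusted p = 0.555 with an estimated correlation). With library totals alone 3 were lower and 1 higher. In total 8509 genes differed, 4288 higher and 4221 lower. Of these 1193 and 889 passed a 2-fold change. The split with library totals alone was 6090 higher and 2685 lower.

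Whether the drugs differed at 1 h was tested as the isoprenaline effect minus the phenylephrine effect, each against its own controls, at doses that were not matched. The cAMP and CREB targets had the stronger response to isoprenaline, with 8 of 18 members higher and 0 lower in the difference (9 and 0 adjusted over the list alone; camera adjusted p = 2.71e-15). Of these 5 were higher without the 4 interferon-high libraries. Rgs2, a regulator of G-protein signalling, rose from 35.2 ± 5.76 to 482 ± 48.8 CPM after isoprenaline. After phenylephrine it stood at 52.9 ± 7.50 CPM against 38.2 ± 6.71, which was not called, except with only the compared groups or the atrial covariate in the fit (0.45 and 0.55 from 0.47). The difference of log2 fold changes was 3.31 (SE 0.24, adjusted p = 6.89e-10). Crem, Pde4d and Nr4a2 also differed toward isoprenaline, by 1.54, 1.24 and 2.48. Hypertrophy and fetal genes differed the other way, 4 of 14 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00173, and adjusted p = 0.212 with an estimated correlation). Xirp1 led them (-2.48), and 1 was higher with only the compared groups in the fit. The response to phenylephrine was also the stronger for the matricellular gene Cyr61 (difference -3.23), the plasminogen activator inhibitor Serpine1 (-2.89) and Rasl11b (-4.17). Edn1 went from 6.14 ± 0.775 to 2.64 ± 0.904 CPM after isoprenaline but from 6.48 ± 0.878 to 33.3 ± 6.06 CPM after phenylephrine (difference -3.58, SE 0.28, adjusted p = 1.04e-09). Of the immediate early genes 6 of 28 were higher and 8 lower in the difference (6 and 12 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.905 with an estimated correlation). No difference was called for the other 14, Fos and Fosb among them. It was -1.07 (95% interval -2.03 to -0.10, adjusted p = 0.201) for Fos, and 0.10 without the 4 interferon-high libraries. It was 0.13 (95% interval -1.21 to 1.46, adjusted p = 0.948) for Fosb. Nor was a difference called for the inflammatory genes Cxcl1 and Nfkbiz, at -0.41 (95% interval -1.01 to 0.19, adjusted p = 0.47) and -0.11 (95% interval -0.46 to 0.24, adjusted p = 0.782). Interferon response genes had 2 of 30 lower and 0 higher in the difference (18 and 0 adjusted over the list alone; camera adjusted p = 4.36e-10, and adjusted p = 0.652 with an estimated correlation). The number lower was 27 without ISO 1 h replicate 1, 14 without ISO control replicate 5, 7 without ISO control replicate 2, 6 with DESeq2 and 0 or 1 without most of the other libraries. Adipocyte markers had 2 of 9 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00562, and adjusted p = 0.652 with an estimated correlation), and 1 higher without the 4 interferon-high libraries or PE control replicate 1. The difference was called for 895 genes, 420 toward isoprenaline and 475 toward phenylephrine. It was called for 528 without the 4 interferon-high libraries, and library totals alone gave 487 higher and 321 lower.

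The overlap of the calls was counted in each direction. At 1 h, 816 genes were higher after both drugs, where independent lists of the same sizes would share 168.7. A further 589 were lower after both, where they would share 135.1. Opposite calls were 6 genes higher after isoprenaline and lower after phenylephrine, and 13 the reverse, against 126.9 and 179.6 for independent lists. At 1 day, 259 genes were higher and 287 lower after both drugs, against 181.8 and 175.5 for independent lists. A further 208 were higher after isoprenaline and lower after phenylephrine and 98 the reverse, against 178.9 and 178.3 for independent lists. Without the 4 interferon-high libraries the lists were shorter, and 66 genes were higher and 62 lower after both drugs, against 28.2 and 20.8 for independent lists of those sizes. Opposite calls were then 19 and 5, against 27.7 and 21.2. Across all tested genes, which are not independent replicates, the log2 fold changes of the drugs had a Pearson correlation of 0.511 at 1 h and 0.183 at 1 day. The drugs had separate control libraries. The labels give no injected vehicle for either control group, so what both drugs share cannot be told apart from a response to the injection.

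At 1 day the drugs differed for 6521 genes. Monocyte and recruited macrophage markers responded more to phenylephrine, with 14 of 15 lower in the isoprenaline minus phenylephrine difference (15 adjusted over the list alone; camera adjusted p = 2.15e-08, and adjusted p = 0.175 with an estimated correlation). So did 21 of 30 cytokines and chemokines (22 adjusted over the list alone; camera adjusted p = 7.69e-08, and adjusted p = 0.133 with an estimated correlation). Neutrophil markers had 7 of 11 lower and 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.264 with an estimated correlation). Resident macrophage markers had 8 of 14 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.00507, and adjusted p = 0.467 with an estimated correlation; adjusted p = 0.133 without the 4 interferon-high libraries). Ccl2 differed by -3.88, and by -3.15 without the 4 interferon-high libraries. Of the matrix list 19 of 23 members were lower in the difference (20 adjusted over the list alone; camera adjusted p = 3.71e-09, and adjusted p = 0.175 with an estimated correlation). In this list 1 was higher, Mmp2 (0.55). That call was lost with library totals alone (0.39) and without ISO control replicate 2, ISO 1 day replicate 2 (0.48 each) or PE 1 day replicate 5 (0.47). All 22 oxidative phosphorylation genes (22 adjusted over the list alone; camera adjusted p = 1.75e-12, and adjusted p = 0.175 with an estimated correlation) and 22 of 27 ion channel and calcium genes (22 adjusted over the list alone; camera adjusted p = 5.31e-11, and adjusted p = 0.0523 with an estimated correlation) were higher in the difference. Ankrd2 (log2 fold change -6.04, SE 0.66, adjusted p = 7.32e-08) and Il1r2 (log2 fold change -5.85, SE 0.73, adjusted p = 4.48e-07) were among the genes that responded more to phenylephrine, and Kcnip2 differed by 2.36. The values were -5.25 for Ankrd2 and -4.69 for Il1r2 without the 4 interferon-high libraries. Il1r2 lay at 0 to 0.364 CPM in the ISO controls and 0.0578 to 0.287 CPM at ISO 1 day. The size of its difference thus rests on few reads, and no counting interval was computed for it. No difference was called for the fatty acid genes Ucp3, at -0.59 (95% interval -1.39 to 0.20, adjusted p = 0.235), and Ehhadh, at 0.27 (95% interval -0.09 to 0.62, adjusted p = 0.228). All 30 interferon response genes were lower in the difference (30 adjusted over the list alone; camera adjusted p = 1.53e-05, and adjusted p = 0.551 with an estimated correlation), and 8 were without the 4 interferon-high libraries and 17 without ISO control replicate 3. Of the called genes 3109 were higher and 3412 lower in the difference. The split was 2102 higher and 4620 lower with library totals alone, and 5036 genes were called without the 4 interferon-high libraries.

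The genes of the receptors themselves moved with the drug and the time. Adrb1 (ENSMUSG00000035283, chromosome 19, 56722372 to 56724862), the main cardiac beta receptor, rose at 1 h after isoprenaline from 22.4 ± 3.87 to 36.2 ± 1.79 CPM (log2 fold change 0.69, SE 0.10, adjusted p = 7.63e-06). It fell at 1 h after phenylephrine from 20.4 ± 0.897 to 11.1 ± 1.53 CPM. The effects differed by 1.57 (SE 0.15, adjusted p = 1.17e-07). At 1 day Adrb1 stood at 23.2 ± 1.86 and 18.9 ± 2.76 CPM and passed neither test against the controls. Adrb2 rose at 1 h after isoprenaline (0.85) and differed between the drugs by 0.94. Adra1d rose too (0.97), and at 0.70 was not called without the 4 interferon-high libraries. Its effects differed by 1.10 (SE 0.33, adjusted p = 0.043). That call was lost without the 4 interferon-high libraries (0.83), with no filter (1.11), with only the compared groups (1.09) and without any 1 of ISO control replicates 2, 3 and 4, ISO 1 h replicates 1, 2 and 3, PE control replicates 1 and 2 and PE 1 h replicates 1, 2, 3 and 5 (0.93 to 1.12). Adra1a fell at 1 day after phenylephrine from 25.1 ± 3.16 to 7.83 ± 1.77 CPM (log2 fold change -1.68, SE 0.14, adjusted p = 1.16e-10), more than after isoprenaline (difference 0.95, SE 0.19, adjusted p = 0.000194). Adra1b fell at 1 day after phenylephrine (log2 fold change -0.42, SE 0.12, adjusted p = 0.0062), a call lost without PE control replicate 3 (-0.29) and with library totals alone (-0.25). Adrb3 ran from 0.0607 to 12.6 CPM within the ISO controls and passed no test.

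**Figure D4:**
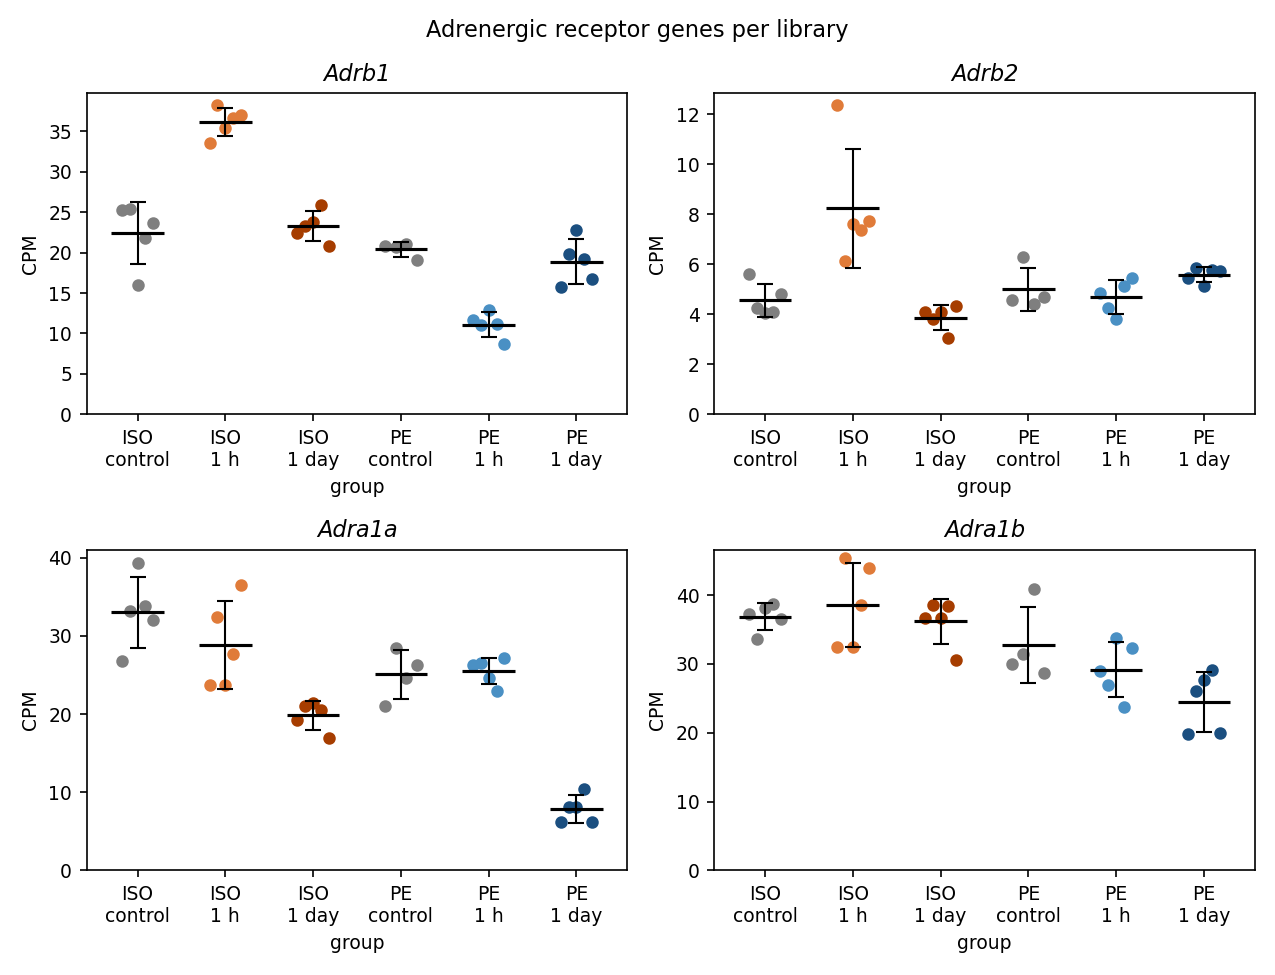
Level of Adrb1, Adrb2, Adra1a and Adra1b in each library, in CPM on a linear axis from 0, by group. Points are libraries and bars are group means with error bars of 1 SD. Adrb1 has its highest mean at 1 h after isoprenaline and its lowest at 1 h after phenylephrine, and Adra1a its lowest at 1 day after phenylephrine.

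The direct comparisons of the times showed how fast each response passed. After isoprenaline 4831 genes differed between 1 day and 1 h, 2464 higher and 2367 lower at 1 day, and 4522 higher and 1279 lower with library totals alone. The cAMP and CREB targets fell back, 14 of 18 lower (14 adjusted over the list alone; camera adjusted p = 7.23e-46). Of the heat shock genes 12 of 14 were lower (12 adjusted over the list alone; camera adjusted p = 2.2e-10, and adjusted p = 0.0538 with an estimated correlation). Aplnr returned from 3.46 ± 0.932 to 50.2 ± 12.6 CPM. After phenylephrine 9381 genes differed, 4722 higher and 4659 lower at 1 day, and 8432 higher and 2252 lower with library totals alone. Of the immediate early genes 25 of 28 were lower at 1 day than at 1 h and 1 was higher (25 and 2 adjusted over the list alone; camera adjusted p = 5.88e-38). The higher gene was Ier3 (0.42), and 2 were higher with DESeq2 or its size factors, library totals alone, a filter at 1 CPM, the atrial covariate, without the 4 interferon-high libraries, or without PE 1 h replicate 1 or 5 or PE 1 day replicate 2 or 4. Of them 21 were still above the controls and 1, Klf4 (-0.56), was below (21 and 1 adjusted over the list alone; camera adjusted p = 6.71e-08, and adjusted p = 0.163 with an estimated correlation). Ier3 and Klf4 were named after their values were seen. Xirp2 (log2 fold change 2.84) and Timp1 (5.40) rose between the times, while Xirp1 (log2 fold change -1.81) fell.

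The control groups were compared to show how far they stood apart before any drug. Interferon response genes were lower in the PE controls, 26 of 30 (30 adjusted over the list alone; camera adjusted p = 7.2e-22, and adjusted p = 0.518 with an estimated correlation). Igtp stood at 545 ± 586 CPM in the ISO controls and 28.7 ± 7.15 CPM in the PE controls, a difference of -4.24 that became 0.46 without the 4 interferon-high libraries and -3.49 without ISO control replicate 3. With only these groups in the fit it was not called (-4.25). Without the 4 libraries 0 of the 30 were called (5 lower and 1 higher at an unadjusted p under 0.05), and 0 with only these groups in the fit (29 lower unadjusted). Neutrophil markers were higher in the PE controls, 4 of 11 (5 adjusted over the list alone; camera adjusted p = 5.77e-05, and adjusted p = 0.518 with an estimated correlation). S100a8 stood at 3.11 ± 1.68 against 0.529 ± 0.263 CPM in the ISO controls, a difference of 2.55. That call was lost without the 4 interferon-high libraries (2.82), ISO control replicate 4 (2.42), or PE control replicate 1 (2.26) or 3 (2.36). Without the 4 libraries 0 of the 11 were called (7 higher at an unadjusted p under 0.05), and 0 without PE control replicate 1 (5 unadjusted). The number was 1 without ISO control replicate 4 or PE control replicate 3 or with only these groups, and 2 without ISO control replicate 2, 3 or 5, with library totals alone or with no filter. Of the red blood cell markers 2 of 6 were higher (3 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.64 with an estimated correlation). The number was 1 without the 4 libraries or without any single control library but PE control replicate 3. It was also 1 with library totals alone, only these groups, robust spread, the replicate number as a block or the atrial covariate. The globin genes are near copies whose reads counting could split. Endothelial markers had 4 of 15 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00192, and adjusted p = 0.64 with an estimated correlation). The number was 1 without ISO control replicate 1 or 4 or PE control replicate 4 or with only these groups. It was 2 without the 4 libraries, ISO control replicate 2 or 5 or PE control replicate 2 or 3, with library totals alone or with no filter. The controls differed for 1047 genes, 485 higher and 562 lower in the PE controls, and 194 higher and 754 lower with library totals alone. The count was 260 without the interferon-high libraries and 201 with only these groups in the fit, 695 without PE control replicate 3 and 660 without PE control replicate 4.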

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

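The tests of explanations and the other splits of the samples in this part were chosen after the results were seen. The tests of the difference between the drugs were fixed before the data were examined.

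In 90 checks of a library measure, a receptor gene or a marker list within a group, 14 had a library that stood far from the rest of its group, where chance gives about 4.5. ISO control replicate 2 had 26.7% of its counts in mitochondrial genes, against 24.2% in the nearest library, and 28.95% in its 10 highest genes, against 26.5%. Its atrial markers had a mean log2 CPM of 2.96, against 7.43, and its red blood cell markers 0.65, against 2.73. ISO 1 h replicate 1 stood at 12.4 CPM for Adrb2, against 7.71, at 19.6 CPM for Adrb3, against 1.99, and at a mean log2 CPM of 5.70 for the interferon list, against 3.60. PE control replicate 1 had 6.46 CPM of Adrb3, against 0.486, and a mean log2 CPM of 5.43 for adipocyte markers, against 1.52. PE control replicate 2 had 6.28 CPM of Adrb2, against 4.68, and PE control replicate 4 had 19.1 CPM of Adrb1, against 20.75. ISO 1 day replicate 5 had 30.6 CPM of Adra1b, against 36.65. PE 1 day replicate 1 had 5.97 CPM of Adra1d, against 3.30. The atrial markers of PE 1 h replicate 3 stood at 0.13, against 3.41.

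The drugs' effects differed for 895 genes at 1 h and 6521 at 1 day. Among the genes named at 1 h, the isoprenaline minus phenylephrine difference on the log2 scale was positive for Rgs2 (3.31), Nr4a2 (2.48), Adrb1 (1.57), Crem (1.54), Pde4d (1.24), Adra1d (1.10) and Adrb2 (0.94). It was negative for Rasl11b (-4.17), Edn1 (-3.58), Cyr61 (-3.23), Serpine1 (-2.89), Xirp1 (-2.48) and the B cell genes Ms4a1 (-4.50), Cd79a (-3.54), Ighd (-2.28) and Cd79b (-2.18). At 1 day it was positive for Kcnip2 (2.36), Hlf (1.65), Tef (1.14), Adra1a (0.95) and Mmp2 (0.55), and negative for Ankrd2 (-6.04), Il1r2 (-5.85), Ccl2 (-3.88), Grk5 (-1.16) and Arrb2 (-1.16).

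Interferon response genes were lower after isoprenaline than in the ISO controls. Scaling of the libraries does not account for this, since the median at 1 day was -1.90 with library totals alone. Raised interferon genes in some ISO control libraries are a candidate explanation that the values at 1 day go with. In the ISO 1 day libraries 0 of 30 members were lower than in the PE controls (1 at an unadjusted p under 0.05). With ISO control replicates 2 and 5 alone 0 (2 unadjusted) were lower at 1 day, against 4 to 30 with the other pairs of ISO controls. A fall at 1 day was thus called only with ISO control replicate 1, 3 or 4 in the fit. ISO control replicates 2 and 5 had the lowest mean log2 CPM of this same list among the ISO controls (4.59 and 3.54). Keeping them alone lowers the control mean by construction. The loss of the fall with that pair, at 1 day or at 1 h, therefore adds no support to the explanation. At 1 h 0 members were lower (1 unadjusted) and 1 was higher than in the PE controls, with a median of 0.46, and 0 (2 unadjusted) were lower than in ISO control replicates 2 and 5 alone. With ISO 1 h replicate 1 also left out 10 were lower. That library was left out for its high level of these same genes, which lowers the treated mean by construction. The 10 members thus do not speak for a drug effect. A fall caused by the drug at 1 h is not decided, and what raised these genes in single control hearts was not tested.

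Atrial and adipocyte markers stood low at 1 h after phenylephrine. Lower sequencing depth is argued against by the mean total of those libraries, which was 0.946 of that of the PE controls. An uneven share of atrial tissue and fat among the hearts may account for it, since the atrial mean log2 CPM ranged over 8.54 among the PE controls, more than the fall in the list's median. An effect of the drug on these genes stays open.

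At 1 day the change was larger after phenylephrine than after isoprenaline, and monocyte, cytokine and matrix genes were among those that differed. Blood left in the PE 1 day hearts is argued against by red blood cell markers, whose median was -0.82. Raised interferon genes in some ISO control libraries are argued against by the 11 of 15 monocyte markers that stayed lower in the difference without the 4 libraries. A lower share of cardiomyocyte RNA alone would raise the markers of every other cell type alike, but the endothelial median was -0.31 where the monocyte median was 3.03. These medians cannot tell whether entering cells lowered the share of both cardiomyocyte and endothelial RNA. Whether the falls in those lists are a matter of cell shares thus stays open. The hypothesis that entry of myeloid cells differs between the drugs stays open, as do the unmatched doses and any difference in handling between the drugs' series, which were not tested.

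Other splits of the same libraries were drawn 100 times per comparison, the real split included, each fitted with the compared groups alone. In each comparison 1 split, the real one, gave as many calls. With 100 splits no share under 1 in 100 can be seen, so chance is made unlikely but is not excluded. For the differences the drug labels were exchanged within treated and within control libraries, which also breaks up any constant offset between the drugs' series. The real and the highest other counts were 3780 and 603 for isoprenaline at 1 h, 761 and 2 at 1 day, 1545 and 189 for phenylephrine at 1 h, and 7964 and 5974 at 1 day. They were 667 and 557 for the difference at 1 h and 6391 and 27 at 1 day. For 1 day against 1 h they were 4803 and 9 after isoprenaline and 8942 and 0 after phenylephrine, and for the control groups 201 and 63.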

How the results depend on the processing

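The alternatives that leave out the 4 interferon-high libraries or adjust for atrial markers were chosen after the data had been seen, and the others before. DESeq2 size factors, DESeq2, the filter at 1 CPM, robust spread and the atrial covariate kept each count of called genes within 1.5 times its value. Leaving out 1 library did so in 102 of 105 refits. Library totals alone gave 3827 calls for phenylephrine at 1 h. No filter gave 668 for the controls. With only the compared groups in the fit, 761 genes were called for isoprenaline at 1 day and 201 for the controls. That fit leaves fewer samples to estimate the spread, which the main fit shares over groups of unequal spread. The SD of the interferon mean log2 CPM was 1.4 in the ISO controls, against 0.21 at ISO 1 day and 0.22 in the PE controls. Between the times after isoprenaline and phenylephrine, without controls, 4803 and 8942 genes were called, against 4831 and 9381. Phenylephrine at 1 h, without ISO controls, gave 1545 against 2061. Where the ISO controls varied most, p-values of the main fit may be too small. Without the 4 interferon-high libraries the counts were 2576 and 184 for isoprenaline at 1 h and 1 day, 528 for the difference at 1 h and 260 for the controls, and 66 and 62 genes were higher and lower after both drugs at 1 day. That fit leaves 2 ISO controls. With any 2 of the 5 ISO controls the calls ran from 2532 to 3926 at 1 h and from 160 to 1308 at 1 day. Leaving out 1 library moved isoprenaline at 1 day between 864 (without ISO control replicate 3) and 1550, and the controls between 660 (without PE control replicate 4; 695 without replicate 3) and 998. A required log2 fold change of 1 left 229 genes higher and 102 lower after both drugs at 1 h, and 24 and 32 at 1 day. Where no reason is given, the cause was not tested.

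With an estimated correlation camera called 5, 0, 6 and 1 lists for isoprenaline at 1 h and 1 day and phenylephrine at 1 h and 1 day, against 13, 13, 14 and 18. It called 1 and 0 for the differences at 1 h and 1 day, against 9 and 20. It called 4 and 2 for the times after isoprenaline and phenylephrine, against 9 and 19, and 0 for the controls, against 6. Immediate early, cAMP and MAP kinase feedback genes, heat shock and hypoxia lists held at 1 h after both drugs, hypertrophy genes at 1 h and 1 day after phenylephrine, and cAMP targets in the difference at 1 h. Immediate early genes and cAMP targets held between the times after both drugs, and MAP kinase feedback and hypoxia genes after isoprenaline. The rotation test fry, which does not compare a list with other genes, called 7 lists for isoprenaline at 1 day, 5 for the difference at 1 h and 1 for the controls. Without the interferon-high libraries camera called 12 for the controls. The atrial list at PE 1 h turned its direction with the atrial covariate (adjusted p = 0.918), which removes that signal by construction. The Fosb difference at 1 h, not called, lay between -0.15 (without PE control replicate 3) and 0.43 with a library left out. Without the interferon-high libraries the Igtp difference between the controls turned from -4.24 to 0.46, and the uncalled Fos difference at 1 h from -1.07 to 0.10. The uncalled change of Adrb1 at 1 day turned to -0.08 after isoprenaline without those libraries and to -0.05 without ISO control replicate 3, and to 0.06 after phenylephrine with library totals.

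The naming rule picked 925 called pairs of a gene and a comparison. Of these calls 64 were lost with library totals, 93 with the compared groups alone, 167 without the interferon-high libraries and 137 when some single library was left out. The text names 143 of the pairs, and 135 kept their call in each planned setting, against 616 of the other 782. The examples were picked with these values in view, and some, among them Ehhadh at 1 day after isoprenaline and Pdk4 and Angptl4 between the controls, were passed over because an alternative ended their call, so the named genes are steadier than the rest.

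The labels share replicate numbers between groups. Deviations of libraries with the same number had a mean correlation of 0.0943 in the isoprenaline series, over 0.1 in 7 of 15 pairs, and -0.0168 in the phenylephrine series, over 0.1 in 2 of 13, and 8 of 29 libraries correlated best with their own number. For libraries with different numbers the mean was -0.0247 in the isoprenaline series, over 0.1 in 13 of 60 pairs. It was 0.0044 in the phenylephrine series, over 0.1 in 10 of 52. A pairing by number was thus not seen in the phenylephrine series and is not decided in the isoprenaline series. With the number as a block the counts in the order of the comparisons were 4738, 1327, 1966, 8190, 846, 6253, 4765, 9288 and 1085, all within 1.5 times, and 28 of the 925 calls were lost. Of the lists in the text, the block ended the calls of immediate early genes in the difference at 1 h and endothelial markers at PE 1 day (adjusted p = 0.0688 and 0.065). It added cytokines at ISO 1 h and adipocyte markers at PE 1 h (0.0397 and 0.0252). Depth limits genes under about 1 CPM, where 1 count is worth 0.0491 to 0.0676 CPM.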

Other observations

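Further gene groups fixed before the data were examined are given here, whether or not the list as a whole passed its test. Targets of the glucocorticoid receptor were higher at 1 h after both drugs, 8 of 16 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 8.28e-08, and adjusted p = 0.156 with an estimated correlation) after isoprenaline and 8 of 16 higher and 0 lower (11 and 1 adjusted over the list alone; camera adjusted p = 1.25e-10, and adjusted p = 0.0638 with an estimated correlation) after phenylephrine. Sgk1, a kinase gene of this list, rose by log2 fold changes of 1.35 and 1.65. Without the 4 interferon-high libraries 10 were higher and 0 lower (0 unadjusted) after isoprenaline, and with library totals alone or only the compared groups 1 was lower after phenylephrine. At 1 day after phenylephrine the list went both ways, and its members Klf9 (-1.26) and Zbtb16 (-2.25) had fallen. Genes of the circadian clock had 4 of 16 higher and 10 lower (4 and 11 adjusted over the list alone; camera adjusted p = 0.00327, and adjusted p = 0.0869 with an estimated correlation) at 1 day after phenylephrine. The clock-controlled transcription factor genes Hlf (log2 fold change -1.37), Tef (-0.87) and Nr1d2 (-0.77) fell, and the difference between the drugs was called for Tef (1.14) and Hlf (1.65). The labels give no sampling time for the controls, so the hour of day of those hearts is not known here.

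The adrenergic receptor and signalling list had 4 of 20 higher and 8 lower (4 and 8 adjusted over the list alone; camera adjusted p = 0.535) at 1 day after phenylephrine, and its median of -0.17 was 0.01 with library totals alone, where 5 were lower. The receptor kinase gene Grk5 went from 31.8 ± 2.49 to 71.8 ± 5.67 CPM (log2 fold change 1.18, SE 0.07, adjusted p = 1.26e-12) and the arrestin gene Arrb2 rose (1.03), while the adenylyl cyclase gene Adcy6 fell (-0.68). Both rises differed between the drugs, by -1.16 and -1.16. Genes of DNA replication and mitosis had 9 of 22 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0736) at 1 day after phenylephrine, with Mcm5 (1.60) and Tyms (1.35) among those that rose. Targets of the oxidative stress factor Nrf2 split, with Hmox1 (2.43) and Txnrd1 (1.13) higher and Gstm1 (-0.98) and Sod2 (-0.82) lower. The list as a whole gave camera adjusted p = 0.453. Of the smooth muscle and pericyte list 2 of 12 were higher and 4 lower at 1 day after phenylephrine (2 and 4 adjusted over the list alone; camera adjusted p = 0.188). The lower genes were Abcc9 (-1.07), Rgs5 (-0.84), Vtn (-0.78) and Kcnj8 (-0.43), and the higher genes were Pdgfrb (0.22) and Cspg4 (0.31), both named after their values were seen. The Pdgfrb call was lost without PE control replicate 1 (0.19), 2 (0.23) or 3 (0.20) or PE 1 day replicate 1 (0.17), 2 (0.21) or 3 (0.22), and with only the compared groups (0.22). The Cspg4 call was lost without PE control replicate 3 (0.27) or 4 (0.30) or PE 1 day replicate 1 (0.20) or 2 (0.28). Genes of zinc finger proteins stood among the largest falls at 1 h after phenylephrine, such as Zfp763 (-2.31), Zfp273 (-2.21) and Zfp39 (-1.76). Zfp273 (-2.48) and Zfp455 (-2.73) fell at 1 h after isoprenaline. Unlike the other groups here, this family was not a list fixed before the data were examined, and no enrichment of it was tested.

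Lymphocyte markers were few and uneven. Of 16 members 4 were lower in the isoprenaline minus phenylephrine difference at 1 h (7 adjusted over the list alone; camera adjusted p = 0.000307, and adjusted p = 0.473 with an estimated correlation), all from B cells: Ms4a1, Cd79a, Cd79b and Ighd. With genes at a mean of 1 CPM or more 2 were lower, and 7 without ISO control replicate 2. The Cd79b call (-2.18) was lost without any 1 of ISO control replicates 4 and 5, ISO 1 h replicates 2 and 5, PE control replicates 2 and 3 and PE 1 h replicate 5, with values from -2.14 to -1.93. It was also lost with the replicate number as a block (-2.04). The Ighd call (-2.28) was lost without any 1 of ISO control replicates 4 and 5, ISO 1 h replicates 2, 4 and 5, PE control replicates 1 and 3 and PE 1 h replicates 1, 4 and 5, with values from -2.25 to -1.95, and with only the compared groups (-2.29). Ms4a1 (-4.50) was -3.88 without ISO control replicate 4 and -5.21 without ISO 1 h replicate 1. Gapdh, often used as a reference gene, ran from 4.75 to 212 CPM over the 29 libraries. Gapdh has many near-identical pseudogenes, so its level here is uncertain.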
